A study of Danio rerio with 15 samples.

How the data were processed

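Gene expression was measured in the outer nuclear layer of the zebrafish retina on 15 one-colour Affymetrix arrays, as the probe set names show. Per the labels, total RNA was isolated with a Pico Pure kit, amplified with a RiboAmp HS kit and labelled with biotin. Per the series description, photoreceptors were lesioned with light and the layer was collected by laser capture. The deposited values are RMA values on a log2 scale, per the submitters' processing notes, which name RMA without a version or settings, and per the values themselves, which ran from 1.592 to 14.51. RMA usually corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set, so a change shared by most genes would not be visible, and differences among dim probe sets are compressed. Amplification of small amounts of RNA favours the 3' ends of transcripts. The difference between the 3' and the 5' GAPDH control probe sets, a measure of that loss, ran from 4.491 to 6.087 log2 units over the arrays.

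The groups follow the source names in the labels. These are unlesioned control retinas (replicates 5, 6 and 7) and lesioned retinas 6, 12, 24 and 48 h after light onset (replicates 2, 3 and 4 at each time), with 3 arrays per group. The sample titles call every sample a control retina, while source names and descriptions separate control from lesioned samples. The number of animals or captured regions behind each array and the hour of the day at capture are not given in the sources used here. If regions of one animal were spread over several arrays, the p-values would be too small.

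The array held 15617 probe sets, of which 115 control probe sets were left out and 15502 were tested. The platform annotation gave 1 gene symbol for 10795 of them, several for 135 and none for 4572. Entrez identifiers matched the RefSeq gene table for 10711 probe sets, which updated 1 symbol. Each of the 8793 genes was represented by its probe set with the highest mean over all arrays, and 1539 genes had more than 1 probe set. No gene was named from a probe set with several symbols. hsp70.3 was measured by a probe set of the kind that can also bind related transcripts, so its values may include other hsp70 genes. rho and hsp70l had no probe set with a single symbol and are not analysed here. No genome was used, so positions are not given.

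Groups were compared with limma (version 3.58.1, R 4.3.3) in 1 fit over all 15 arrays, with 10 residual and 2.2 prior degrees of freedom. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets of a comparison. The 4 lesioned groups were compared with control, each time point was compared with the one before it, and a moderated F test took the 4 comparisons with control together. Changes are log2 differences, with the standard error (SE) of the fit where given. Group levels are means ± SD over 3 arrays. These comparisons, their alternatives, the gene lists and the rule for naming genes were fixed before the data were examined.

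The 25 gene lists were rod and cone phototransduction, photoreceptor transcription factors, cell cycle, Müller glia, retinal reprogramming (factors with a known role in Müller glia during fish retina regeneration), apoptosis and p53, heat shock and ER stress, immediate early genes, inflammation and JAK-STAT, microglia and leukocytes, retinal pigment epithelium, bipolar cells, amacrine, ganglion and horizontal cells, lens crystallins, erythrocytes, circadian clock, Notch, extracellular matrix and wounding, growth factors, glycolysis, ribosomal proteins, proteasome, oxidative phosphorylation and histones. Some genes are in several lists, such as hspd1, socs3b, jak1 and nr2e3. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over 175 tests (25 lists and 7 comparisons). camera with an estimated correlation, and fry, which asks whether a list's genes moved one way on balance, were run beside it. A list whose genes moved both ways may pass none of these. Member counts use the adjustment over all probe sets, and counts adjusted over the list alone stand beside them. A list of 23 skeletal muscle genes was added after the values had been seen.

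The genes named are the 8 largest rises and 8 largest falls against control (5 and 5 between successive times) among called genes whose group values did not overlap, leaving out placeholder names, and up to 4 called members of each list, some of which are given only in counts. Where no gene passed, the 3 with the smallest p are given as values. Of a list with no called member, up to 2 members with the highest level are given. Photoreceptor, glial and proliferation markers set in advance are given wherever measured, though some not at every time. A gene named in one comparison may be given in others. Members named to complete counts of 5 or fewer were chosen after their values were seen.

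The fit was tested on simulated data with 200 of the 15502 probe sets changed by 1, 2, 3 or 4 log2 units. It recovered 60, 86, 94 and 98% of them at 6 h, 74, 94, 100 and 96% at 12 h, 50, 84, 98 and 100% at 24 h, and 54, 90, 94 and 100% at 48 h, with 7, 8, 9 and 5 false calls. The simulated noise was normal and independent between probe sets, without effects that an array's probe sets share. The percentages may therefore be too high for the real arrays. Each time was simulated with the same settings, so differences between times show only the spread of the simulation. Unchanged groups, controls included, were simulated 50 times to estimate what a shared control group adds to correlations between changes. The alternatives were a repeated quantile normalization, centring on the median, filters on dim probe sets, an intensity trend with a robust prior, array weights, a 2-fold minimum, fits of only the 6 arrays compared, 1 adjustment over the 4 comparisons with control, the replicate number as a block, leaving out each array, another probe set per gene and other list tests. Covariates for GAPDH and for muscle genes, and leaving out 3 arrays rich in muscle RNA, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.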

Results

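The study asked which genes photoreceptor regeneration requires in zebrafish (Danio rerio), a fish that replaces photoreceptors after they die. Expression was measured in the outer nuclear layer, the layer that holds the cell bodies of rods and cones, in 3 unlesioned control samples and in 3 samples each at 6, 12, 24 and 48 h after the onset of a lesioning light. The 15 arrays had medians between 3.279 and 3.366 log2 units. Nothing in the labels says whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and unlesioned samples from later hours were not used here. Time after light onset, light and, at some of the times, the hour of the day therefore changed together. If the controls were taken at the hour of light onset, the 24 and 48 h samples would share their hour of the day.

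Against control, limma called 803 of 15502 probe sets at 6 h (396 higher and 407 lower), 500 at 12 h (251 and 249), 596 at 24 h (297 and 299) and 220 at 48 h (112 and 108). The F test over the time course called 918 probe sets, 634 of them representing named genes. It called 596 without control replicate 5 and 525 without control replicate 6.

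**Figure D1:**
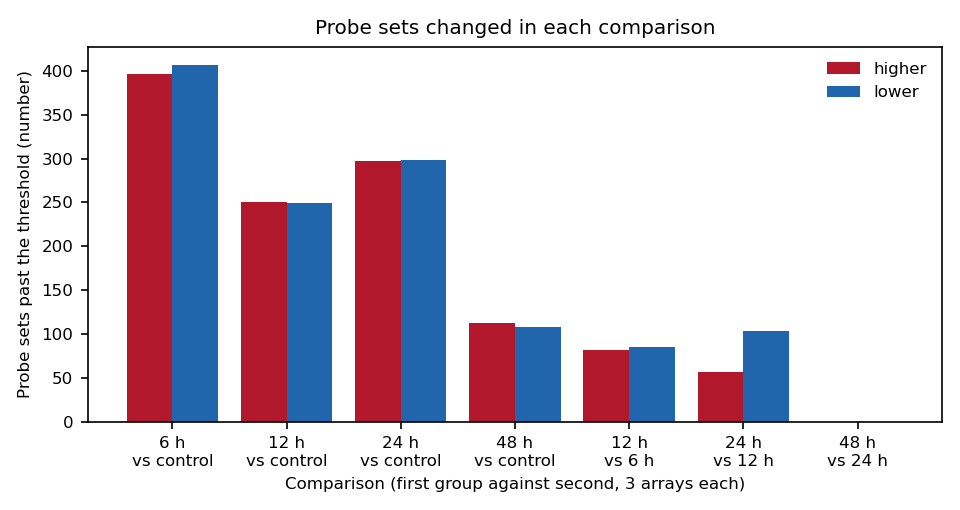
Number of probe sets (y axis) called higher or lower by limma at an adjusted p under 0.05 in each of the 7 comparisons (x axis), with separate bars for higher and lower. The comparison of 6 h with control had 396 higher and 407 lower, and that of 48 h with 24 h had 0.

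At 6 h, 16 of 49 heat shock genes and 6 of 40 immediate early genes rose, and 4 cone opsin genes fell, of which opn1mw1 and opn1lw1 did not pass in every fit. per2, a light-induced repressor of the circadian clock, rose by 6.43 ± 0.41 (SE, 86-fold, adjusted p = 8.74e-06), from 4.65 ± 1.06 in control to 11.08 ± 0.11 (SD, n = 3 each). The chaperone genes hsp70.3 and dnajb1b rose by 5.12 ± 0.68 (34.7-fold, adjusted p = 0.00122) and 4.79 ± 0.60 (27.6-fold, adjusted p = 0.000833). opn1mw2, a green-sensitive cone opsin, fell by 3.66 ± 0.40 (12.6-fold, adjusted p = 0.000384), from 13.62 ± 0.08 to 9.96 ± 0.84. cita, which encodes a citron kinase, fell by 4.81 ± 0.36 (adjusted p = 2.62e-05).

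Of 49 heat shock and ER stress genes, 16 rose at 6 h, 0 fell and 33 did not pass, against 21 and 1 adjusted over the list alone. Besides hsp70.3 and dnajb1b, the HSP90 co-chaperone gene ahsa1b rose by 3.39, the mitochondrial chaperone genes hspe1 and hspd1 by 3.09 and 2.59, and hspa5, the chaperone of the endoplasmic reticulum, by 2.04. The list lay above other genes (median 0.82, camera adjusted p = 1.07e-10, adjusted p = 0.373 with an estimated correlation). Of 40 immediate early genes, which respond within minutes to stimuli, 6 rose (atf3, jun, ier5, dusp5, npas4a and junbb) and dusp1 fell, against 7 and 1 adjusted over the list alone (median 0.09, adjusted p = 0.00561, adjusted p = 0.63 with an estimated correlation). atf3 and jun, stress-activated transcription factors, rose by 4.93 ± 0.82 and 3.69 ± 0.49. Of 37 apoptosis and p53 genes, 5 rose (gadd45ga, gadd45bb, mcl1b, baxa and ccng1) and 0 fell, against 7 and 0 adjusted over the list alone (median 0.08, adjusted p = 0.0243, adjusted p = 0.373 with an estimated correlation). The growth-arrest gene gadd45ga rose by 3.71 ± 0.28 (adjusted p = 3.21e-05) and the survival gene mcl1b by 1.48. Leaving out 1 array ended the calls of baxa (adjusted p = 0.151 without control replicate 6), gadd45bb (0.0807 without 6 h replicate 3) and dusp1 (0.0882 without control replicate 5).

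Of 19 cone phototransduction genes, 5 fell at 6 h and 1 rose, against 9 and 2 adjusted over the list alone (median -0.93, adjusted p = 0.00251, adjusted p = 0.439 with an estimated correlation). The 5 were the opsins opn1mw1, opn1mw2, opn1lw1 and opn1sw2 and the transducin subunit gngt2b. opn1mw1 fell by 5.14 ± 1.06 and the red-sensitive opsin opn1lw1 by 3.27 ± 0.80, but without control replicate 6 their adjusted p rose to 0.0736 and 0.104. The gene that rose was rcvrn3, a recoverin, by 2.71 ± 0.42 (adjusted p = 0.00301). The ultraviolet opsin opn1sw1 did not pass (-1.42, adjusted p = 0.283). Of 14 rod genes only nr2e3, a transcription factor of rod precursors that 2 lists hold, passed, with a fall of 1.77 ± 0.35 that did not pass without control replicate 6 (adjusted p = 0.0549). The median of the rod list was -0.17 (adjusted p = 0.3), and gnat1, rod transducin, changed by -0.21 (adjusted p = 0.879). neurod1, a transcription factor of photoreceptor precursors, fell by 1.36 ± 0.23 (adjusted p = 0.00461). six6b rose by 2.82 (adjusted p = 0.0194, 0.0784 without control replicate 5). The list of 19 photoreceptor transcription factors, with 2 lower and 1 higher (3 and 1 adjusted over the list alone), did not pass (adjusted p = 0.304).

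Proteasome genes fell at 6 h, 11 of 50, with 0 rising (16 and 1 adjusted over the list alone). They included psmd5 (-0.93), psmb10 (-1.30), psmd13 (-1.06) and psma2b (-0.95), and the median was -0.42 (adjusted p = 1.33e-06, adjusted p = 0.373 with an estimated correlation). Except for psmd5 these calls ended without 1 control array (adjusted p = 0.106 and 0.083 for psmb10 and psmd13 without replicate 6, and 0.0584 for psma2b without replicate 5). Of 85 oxidative phosphorylation genes 9 fell and 3 rose, against 24 and 4 adjusted over the list alone (median -0.52, adjusted p = 9.25e-07, adjusted p = 0.696 with an estimated correlation). The 3 that rose, sdha (1.78 ± 0.15, adjusted p = 6.31e-05), sdhb (1.09) and sdhaf3 (1.04), encode parts or an assembly factor of complex II. Those that fell encode parts of complex I, cytochrome oxidase and ATP synthase, such as cox4i2 (-2.03 ± 0.32), ndufb9 (-1.28) and atp5mc3b (-1.25). ndufb9 and atp5mc3b did not pass without control replicates 5 and 6 (adjusted p = 0.0618 and 0.121). Of 69 cell cycle genes, rrm1 rose (2.83-fold) and rpa1 fell by 0.90 (adjusted p = 0.119 without control replicate 5), the same numbers as adjusted over the list alone, with a median of -0.16 (adjusted p = 0.0485, adjusted p = 0.646 with an estimated correlation). pcna, a marker of DNA replication, changed by 0.11 (adjusted p = 0.892).

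Clock genes moved in both directions at 6 h, 9 of 34 higher and 3 lower, against 12 and 6 adjusted over the list alone (median 0.30, adjusted p = 0.00918, adjusted p = 0.62 with an estimated correlation). The bZIP repressor gene nfil3-5 rose by 3.97 ± 0.58 (15.6-fold), and bmal1a, a core activator of the clock, by 3.04. bhlhe41, a repressor that feeds back on the clock, fell by 5.04 ± 0.55 (32.9-fold, adjusted p = 0.00038), and the other lower genes were ciarta and cry2. Outside the lists, dhrs13a.1 rose by 3.83 ± 0.25 (adjusted p = 8.95e-06) and prxl2b by 4.03 ± 0.59, while nptna fell by 4.21 ± 0.39 and mical3b by 4.68 ± 0.43. kera and insb, which encode keratocan and insulin, fell by 5.43 ± 1.27 and 5.06 ± 1.08, with adjusted p of 0.0949 without control replicate 5 and 0.08 without control replicate 6. Of 66 growth factor genes id2a, an inhibitor of differentiation factors, fell by 4.06 ± 0.38 and lef1 by 0.96, and the list did not pass (adjusted p = 0.84).

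The mean of 23 skeletal muscle genes differed with these groups, at 5.54 ± 1.99 at 6 h and 3.92 ± 1.08 in control, with 22 of the 23 higher (median 1.85, 0 called higher and acta1a called lower). Replicates 3 and 4 at 6 h and control replicate 5 had the highest means (7.613, 5.338 and 5.165). Without these 3 arrays, 251 probe sets were called at 6 h, with 10 heat shock genes higher and 1 proteasome gene lower (medians 0.68 and -0.19). In that fit atf3, prxl2b and nfil3-5 changed by 5.27, 4.07 and 4.07 and did not pass (adjusted p = 0.0798, 0.0891 and 0.0836). opn1mw1, opn1lw1 and insb changed there by -5.96, -1.78 and -4.36, against -5.14, -3.27 and -5.06 with all arrays. With the muscle covariate they changed by -4.305, -3.16 and -4.78 and did not pass (adjusted p = 0.0748, 0.106 and 0.0715). In all, 20 of 53 named calls passed without the 3 arrays and 37 with the covariate. The 803 calls became 456, 434 and 504 without control replicate 5, control replicate 6 and 6 h replicate 2. Of these 53, 31 passed whichever array was left out.

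At 12 h, 6 of 34 clock genes and 2 of 19 cone genes fell. bhlhe41 and bhlhe40, related clock repressors, fell by 7.31 ± 0.55 (159-fold, adjusted p = 2.2e-05) and 6.87 ± 0.50 (117-fold, adjusted p = 1.86e-05). nr1d2b, a nuclear receptor that represses bmal genes, fell by 5.32 ± 0.34 (39.9-fold, adjusted p = 8.64e-06), from 9.56 ± 0.12 to 4.24 ± 0.88 (SD, n = 3 each). per2 rose by 5.18 ± 0.41 (36.3-fold), and crtac1a, a gene of an extracellular matrix protein, by 4.42 ± 0.35 (21.3-fold), both at an adjusted p of 2.59e-05. pde6c, the catalytic subunit of cone phosphodiesterase, fell by 2.27 ± 0.18 (4.84-fold, adjusted p = 2.59e-05).

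Of 34 clock genes, 5 rose at 12 h (per2, nfil3-5, bmal1a, bmal2 and cry3a) and 6 fell, against 10 and 7 adjusted over the list alone. As a list they did not pass camera, which looks for a common direction (median 0.15, mean -0.12, adjusted p = 0.792). Tested by fry for change in either direction, without comparison with other genes, the list had an adjusted p of 4.1e-10. Other lists passed this fry test too, such as growth factors (adjusted p = 3.59e-09) and cell cycle (0.000104, with 1 higher and 1 lower of 69 called). It therefore does not single out the clock genes. nfil3-5 rose by 3.90 and bmal1a by 3.38 ± 0.30 (10.4-fold), and ciarta, cry2 and csnk1da were among those that fell. Of 19 cone genes 2 fell, against 11 adjusted over the list alone and 0 higher (median -0.89, adjusted p = 2.7e-06, adjusted p = 0.373 with an estimated correlation). They were pde6c and the cone transducin gene gnat2, which fell by 2.45 ± 0.37 (5.44-fold, adjusted p = 0.00347). nr2e3 fell by 3.33 ± 0.35 (10.1-fold, adjusted p = 0.000269), the only called gene among 19 photoreceptor transcription factors (2 lower adjusted over the list alone, median -0.18, adjusted p = 0.0495, adjusted p = 0.566 with an estimated correlation). The rod list did not pass (median -0.040, adjusted p = 0.24).

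**Figure D2:**
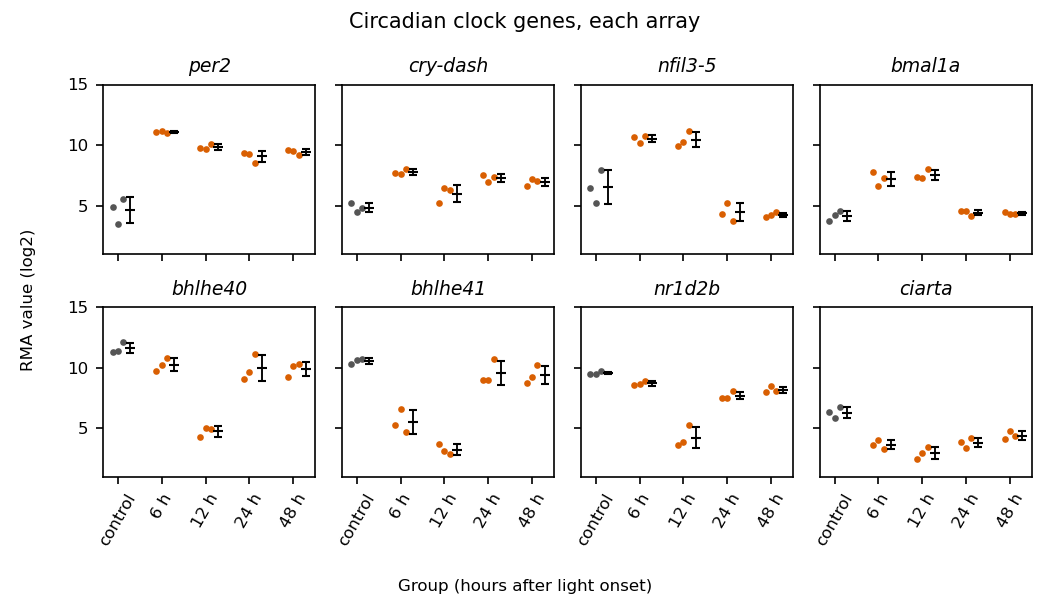
Levels of 8 clock genes (y axes, RMA values in log2) in control and at 6, 12, 24 and 48 h after light onset (x axes), with each array as a point and the group mean ± SD as a bar. bhlhe40 lay at 11.63 in control, 4.76 at 12 h and 9.95 at 24 h, and per2 rose from 4.65 in control to 11.08 at 6 h.

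Of 49 heat shock and ER stress genes, 8 rose and hsf2 fell at 12 h, against 12 and 2 adjusted over the list alone (median 0.40, adjusted p = 1.81e-05, adjusted p = 0.373 with an estimated correlation). hspe1 rose by 2.07 (adjusted p = 0.00216), while dnajb1b (3.25), hsp70.3 (2.73), ahsa1b (1.83) and hspd1 (1.52) passed but lost their calls without 1 array (adjusted p = 0.0601 for dnajb1b without control replicate 6, 0.176 and 0.12 for hsp70.3 and ahsa1b without control replicate 5, and 0.0852 for hspd1 without 12 h replicate 3). atf3 rose by 4.97 (31.3-fold), jun by 3.86 and ier5, an immediate early gene, by 4.12 ± 0.36 (17.4-fold, adjusted p = 6.33e-05). The immediate early list (5 higher and 1 lower of 40, 8 and 2 adjusted over the list alone) and the apoptosis list (gadd45ga and baxa higher, 5 and 1 adjusted over the list alone) did not pass (adjusted p = 0.12 and 0.3), and baxa lost its call without control replicate 6 (adjusted p = 0.0967).

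Of 66 growth factor genes, 4 fell at 12 h (id2a, etv5a, mdka and lef1), against 6 lower and 2 higher adjusted over the list alone (median -0.089, adjusted p = 0.0173, adjusted p = 0.373 with an estimated correlation). The Wnt effector gene lef1 fell by 1.08 and id2a by 3.66, and each passed in every fit that left out 1 array. mdka, which encodes the growth factor midkine, fell by 1.47 and etv5a by 2.06, with adjusted p of 0.179 without 12 h replicate 3 and 0.0924 without control replicate 5. The 7 histone genes were all lower with 0 called (median -0.56, adjusted p = 0.0151, adjusted p = 0.373 with an estimated correlation). In the oxidative phosphorylation list sdha rose and 0 of 85 fell, as adjusted over the list alone (median -0.32, adjusted p = 0.00089, adjusted p = 0.785 with an estimated correlation). Of 41 reprogramming genes 4 rose (tgif1, socs3b, jak1 and hspd1) and mdka fell (5 and 1 adjusted over the list alone, adjusted p = 0.827). Without 12 h replicate 3 socs3b and hspd1 did not pass (adjusted p = 0.151 and 0.0852), nor jak1 without control replicate 6 (0.0935). tgif1, a repressor in TGF-beta signalling, rose by 1.74 (adjusted p = 0.00799). Of 69 cell cycle genes kif20a, a mitotic kinesin gene, fell by 3.18 and rrm1 rose by 1.305 (adjusted p = 0.0823 without control replicate 5), as adjusted over the list alone. At 24 and 48 h 0 of 69 were called. The cell cycle list did not pass camera at 12, 24 or 48 h (adjusted p = 0.213, 0.164 and 0.67), and pcna was not called at these times. Among other genes itm2cb, aqp8a.1 and angptl4 fell by 4.79, 4.67 and 3.74. insb fell by 5.44 (43.4-fold) and the transcription factor gene mef2ca by 4.14, neither passing without control replicate 6 (adjusted p = 0.0806 and 0.055). inhbb, an activin subunit, rose by 4.43 ± 0.89 but lost its call without 12 h replicate 3 (adjusted p = 0.0858).

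The 500 calls at 12 h became 252, 247 and 224 without control replicate 5, control replicate 6 and 12 h replicate 3, and 243 without the 3 arrays rich in muscle RNA. Of 46 named calls, 24 passed whichever array was left out, and 26 without the 3 arrays. The muscle list mean was 3.77 ± 0.55 at 12 h, and the GAPDH difference 5.07 ± 0.24 against 4.98 ± 0.54 in control.

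At 24 h, 7 of 14 rod genes and 4 of 19 cone genes fell, and 7 of 40 immediate early genes rose. gngt1, the gamma subunit of rod transducin, fell by 3.48 ± 0.47 (11.2-fold, adjusted p = 0.00271), from 12.94 ± 0.07 to 9.46 ± 1.28 (SD, n = 3 each). unc119.2, whose product helps transducin reach the outer segment, fell by 3.35 (adjusted p = 0.01) and opn1mw2 by 2.86 ± 0.40 (7.24-fold, adjusted p = 0.0039). atf3 and jun rose by 5.65 ± 0.82 (50.2-fold, adjusted p = 0.00482) and 4.33 (20.2-fold, adjusted p = 0.00116).

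Of 14 rod phototransduction genes, 7 fell at 24 h and 0 rose, against 9 and 0 adjusted over the list alone (median -1.54, adjusted p = 8.56e-08, adjusted p = 0.373 with an estimated correlation). They were gngt1, gnb1a (-3.37), pde6a (-2.55), rom1b (-2.40), gnb1b (-2.04), gnat1 (-2.01) and gucy2f (-1.80), most of which carry the light signal from rhodopsin to the cation channel. Without 24 h replicate 2 pde6a and rom1b did not pass (adjusted p = 0.0862 and 0.0676), nor did gnb1a without control replicate 6 (adjusted p = 0.0732). Of 19 cone genes 4 fell (opn1lw1, opn1mw2, opn1sw2 and gngt2b) and rcvrn3 rose, against 7 and 1 adjusted over the list alone (median -1.10, adjusted p = 4.7e-05, adjusted p = 0.373 with an estimated correlation). opn1sw2, the blue-sensitive opsin, fell by 1.86 (adjusted p = 0.00242), and opn1lw1 by 4.53 ± 0.80 (23.1-fold, adjusted p = 0.012), though not without 24 h replicate 2 (adjusted p = 0.0577). gnat2, opn1mw1 and opn1sw1 did not pass (-1.16, -2.10 and -1.64, adjusted p = 0.107, 0.297 and 0.193). The GAPDH difference moved with these lists, at 5.64 ± 0.42 at 24 h and 4.98 ± 0.54 in control. With it as a covariate 3 rod and 2 cone genes fell, with medians of -1.20 and -0.76. Without the 3 arrays rich in muscle RNA 2 rod genes fell (median -1.66). Among photoreceptor transcription factors rx2 fell (3.99-fold) and six6b rose, the latter not without control replicate 5 (adjusted p = 0.146, and 0.332 for the list of 19, with 1 lower and 1 higher adjusted over the list alone).

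**Figure D3:**
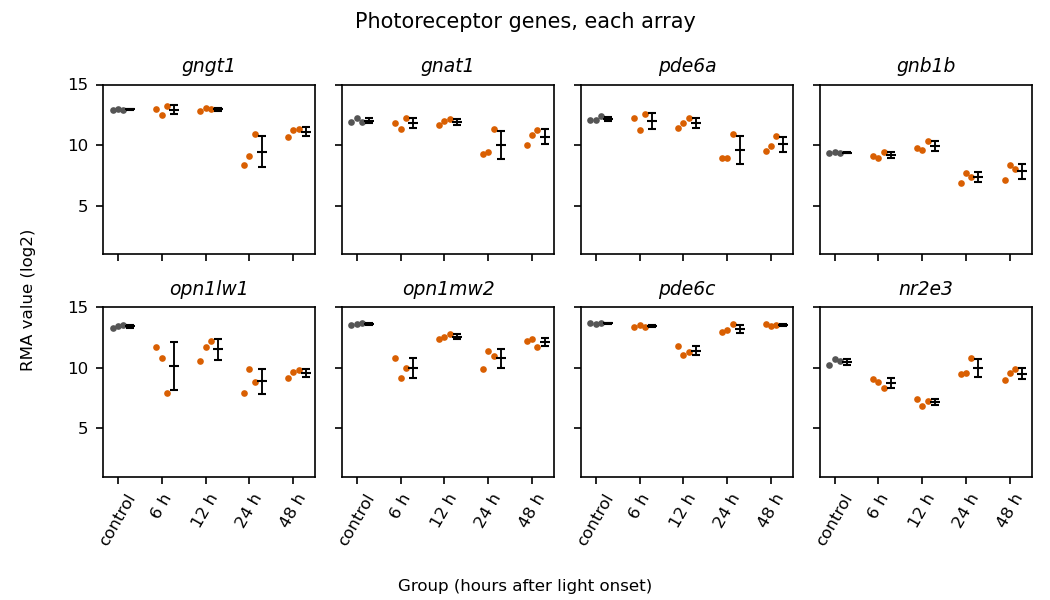
Levels of the rod genes gngt1, gnat1, pde6a and gnb1b, the cone genes opn1lw1, opn1mw2 and pde6c and the transcription factor gene nr2e3 (y axes, RMA values in log2) in control and at 6, 12, 24 and 48 h (x axes), with arrays as points and the group mean ± SD as a bar. gngt1 averaged 12.96 at 12 h and 9.46 at 24 h, whereas pde6c averaged 11.39 at 12 h and 13.21 at 24 h.

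Of 40 immediate early genes, 7 rose at 24 h and 0 fell, against 11 and 2 adjusted over the list alone (median 0.37, adjusted p = 0.000826, adjusted p = 0.537 with an estimated correlation). ier5 rose by 2.86, and fosab by 3.59, the latter not without control replicate 6 (adjusted p = 0.126). Of 49 heat shock and ER stress genes 7 rose, such as hspe1 (4.61-fold) and hspd1 (1.99), and 0 fell, against 16 and 0 adjusted over the list alone (median 0.41, adjusted p = 1.45e-06, adjusted p = 0.373 with an estimated correlation). With the GAPDH covariate 3 immediate early and 2 heat shock genes rose, which alone does not show smaller changes. Of the 55 list calls over all comparisons, 46 stayed with this covariate and 9 did not. Of 38 inflammation genes, socs3b (2.95), nfkb2 (3.35-fold) and jak1 (1.69) rose and 0 fell, against 8 and 1 adjusted over the list alone (median 0.32, adjusted p = 0.00739, adjusted p = 0.668 with an estimated correlation). Each lost its call without 1 array (adjusted p = 0.123 and 0.182 for socs3b and jak1 without 24 h replicate 2, and 0.122 for nfkb2 without control replicate 6). lyz, lysozyme of phagocytes, rose by 4.05 ± 0.92 (16.6-fold, adjusted p = 0.0334, 0.114 without 24 h replicate 2) as the 1 called gene of 29 microglia and leukocyte genes, also adjusted over the list alone (median 0.39, adjusted p = 0.016, adjusted p = 0.695 with an estimated correlation).

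Of 78 ribosomal protein genes 73 were higher at 24 h, but rpl7l1 alone was called (1.39, adjusted p = 0.0765 without 24 h replicate 2), also adjusted over the list alone (median 0.31, adjusted p = 0.000941, adjusted p = 0.796 with an estimated correlation). In the oxidative phosphorylation list atp5mj, ndufs1 and atp5pb fell by 1.05, 1.04 and 0.85 and the complex II genes sdha (1.45) and sdhaf4 (0.82) rose, against 12 and 4 adjusted over the list alone (median -0.45, adjusted p = 3.02e-06, adjusted p = 0.696 with an estimated correlation). Each of those 3 falls lost its call without 1 array (adjusted p = 0.174 for atp5mj without 24 h replicate 2, and 0.171 and 0.127 for ndufs1 and atp5pb without control replicate 6). cry-dash, a light-responsive cryptochrome gene, rose by 2.43 and per2 by 4.41, while ciarta fell by 2.46 (5 higher and 3 lower of 34 clock genes, 6 and 8 adjusted over the list alone, adjusted p = 0.202 for the list). gadd45ga, gadd45ba and baxa rose among 37 apoptosis genes (5 higher adjusted over the list alone), and jak1, mdka, hspd1 and socs3b among 41 reprogramming genes (8 higher adjusted over the list alone), lists that did not pass (adjusted p = 0.097 and 0.0619). Without 24 h replicate 2 gadd45ba and baxa did not pass (adjusted p = 0.0976 and 0.0668), nor mdka without control replicate 6 (0.0964). The glutamine synthetase gene glulb, a Müller glia marker, rose by 2.47 (adjusted p = 0.0903 without 24 h replicate 3), while its paralogue glula and the glial filament gene gfap did not pass (-0.19 and 0.22). The gfap probe set was dim, so a change of gfap could be missed. smtnb fell by 3.11 ± 0.39 and cita by 3.57, and crtac1a rose by 3.52. kera fell by 5.43 ± 1.27 and zdhhc2 by 3.28 ± 0.62, and scg2a, a secretogranin gene, rose by 3.32 ± 0.77. Without 24 h replicate 2 these 3 did not pass (adjusted p = 0.128, 0.0705 and 0.134).

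The 596 calls at 24 h became 156, 198, 954, 217 and 203 without 24 h replicates 2, 3 and 4 and control replicates 5 and 6, and 113 with the GAPDH covariate. They became 228 without the 3 arrays rich in muscle RNA, and 20 of 57 named calls passed whichever array was left out and 28 without those 3.

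At 48 h, 4 of 40 immediate early genes and 2 of 29 leukocyte genes rose, and neither list passed with an estimated correlation. per2 rose by 4.80 (27.9-fold, adjusted p = 0.000186), jun by 4.04 (16.5-fold, adjusted p = 0.00284) and crtac1a by 3.36 (adjusted p = 0.00117). rcvrn3 rose by 3.18 (adjusted p = 0.00401), from 6.84 ± 1.09 to 10.02 ± 0.09 (SD, n = 3 each). cita and vim fell by 2.80 and 1.88 (adjusted p = 0.0036 and 0.00287).

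Of 29 microglia and leukocyte genes, apoc1 (2.58 ± 0.55) and the galectin gene lgals9l1 (2.54 ± 0.47) rose at 48 h and 0 fell, against 9 and 0 adjusted over the list alone (median 0.85, adjusted p = 6.28e-07, adjusted p = 0.373 with an estimated correlation), and 25 of the 29 were higher. apoc1 did not pass without 48 h replicate 2 (adjusted p = 0.17), nor lgals9l1 without control replicate 6 (0.0892). The lipid carrier gene apoeb (1.74, adjusted p = 0.11) and lyz (4.09, adjusted p = 0.0517) did not pass. Of 13 pigment epithelium genes, the melanosome gene pmelb rose by 2.93 ± 0.62 (adjusted p = 0.157 without control replicate 6), against 7 higher adjusted over the list alone (median 0.75, adjusted p = 0.009, adjusted p = 0.373 with an estimated correlation). Ribosomal protein genes were higher in 76 of 78 cases with 0 called either way (median 0.51, adjusted p = 3.83e-10, adjusted p = 0.696 with an estimated correlation).

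Of 41 reprogramming genes, 4 rose at 48 h (sox11b, sox11a, lgals2a and hspd1) and 0 fell, against 8 and 0 adjusted over the list alone (median 0.13, adjusted p = 0.00667, adjusted p = 0.373 with an estimated correlation). sox11b and sox11a, transcription factors of neural progenitors, rose by 4.44 ± 0.88 (21.7-fold) and 8.58-fold, with adjusted p of 0.13 and 0.146 without 48 h replicate 2. In the same fit hspd1 had 0.124, and lgals2a had 0.118 without control replicate 6. ascl1a and stat3, regulators of Müller glia reprogramming, did not pass at any time (0.39 and 0.13 at 48 h, adjusted p = 0.843 and 0.927). These values come from the captured outer nuclear layer and do not show whether the genes changed in other layers. Of 43 amacrine, ganglion and horizontal cell genes, 3 rose at 48 h and 0 fell, as adjusted over the list alone, and the list did not pass (median 0.058, adjusted p = 0.205). They were gap43, tubb5 and snap25a, of axon growth, microtubules and synapses, which rose by 2.24 ± 0.40, 4.61-fold and 2.85 ± 0.54, with adjusted p of 0.0842 without 48 h replicate 3, 0.0841 without 48 h replicate 2 and 0.106 without control replicate 6.

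**Figure D4:**
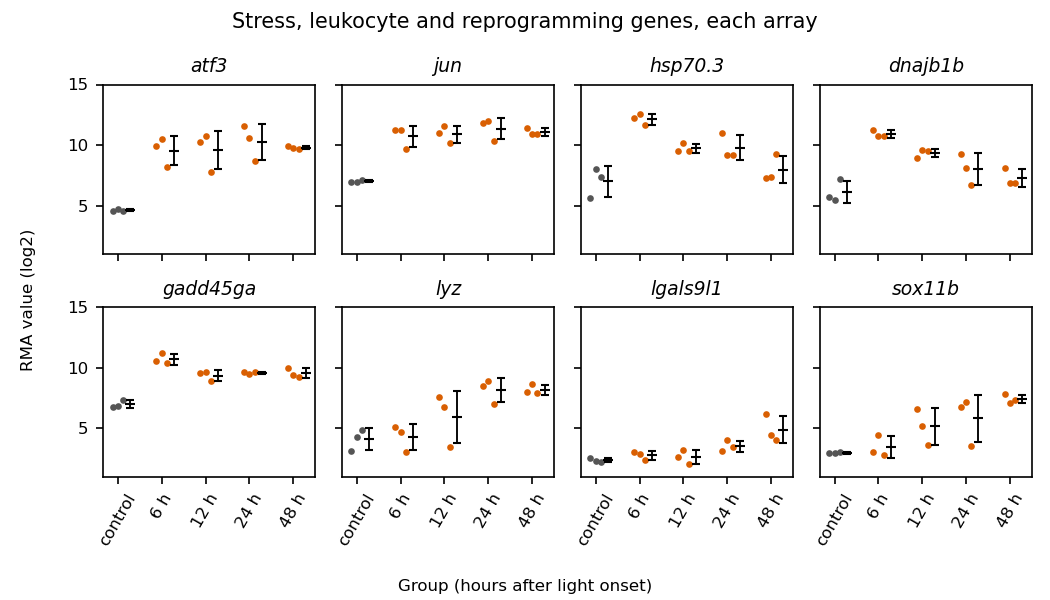
Levels of atf3, jun, hsp70.3, dnajb1b, gadd45ga, lyz, lgals9l1 and sox11b (y axes, RMA values in log2) in control and at 6, 12, 24 and 48 h (x axes), with arrays as points and the group mean ± SD as a bar. hsp70.3 averaged 12.13 at 6 h and 7.99 at 48 h, and sox11b 2.97 in control and 7.41 at 48 h.

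Of 14 rod genes gnb1b alone fell at 48 h (1 against 9 adjusted over the list alone), by -1.55 (adjusted p = 0.111 without control replicate 6), with the list below other genes (median -1.16, adjusted p = 7.08e-06, adjusted p = 0.385 with an estimated correlation). The cone list did not pass (median -0.34, adjusted p = 0.164, opn1lw1 lower and rcvrn3 higher, 3 and 1 adjusted over the list alone), and opn1lw1, which fell by 3.87, lost its call without 48 h replicate 2 (adjusted p = 0.145). Of 40 immediate early genes atf3 (5.15), jun, fosab (3.98) and ier5 (2.47) rose, against 8 higher and 1 lower adjusted over the list alone (median 0.28, adjusted p = 0.00183, adjusted p = 0.579 with an estimated correlation). atf3 and fosab did not pass without 48 h replicate 2 and control replicate 6 (adjusted p = 0.0569 and 0.147). gadd45ga (2.55) and baxa (1.56, adjusted p = 0.173 without control replicate 6) rose among 37 apoptosis genes, against 6 higher and 1 lower adjusted over the list alone (median 0.12, adjusted p = 0.0271, adjusted p = 0.373 with an estimated correlation).

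Of 49 heat shock and ER stress genes txnb, hspe1 and hspd1 rose at 48 h, by 3.77, 1.81 and 1.61, against 4 adjusted over the list alone (median 0.29, adjusted p = 0.00024, adjusted p = 0.461 with an estimated correlation), with adjusted p of 0.125, 0.0626 and 0.124 without 48 h replicate 2. In the oxidative phosphorylation list sdha (1.28) and sdhaf4 (1.05, adjusted p = 0.0998 without 48 h replicate 2) rose and 0 fell, as adjusted over the list alone (median -0.28, adjusted p = 0.000998, adjusted p = 0.785 with an estimated correlation). The glycolytic gene eno1b fell by 1.59 (adjusted p = 0.13 without 48 h replicate 2) as the 1 called gene of 28 glycolysis genes, against 6 adjusted over the list alone (median -0.33, adjusted p = 0.0232, adjusted p = 0.502 with an estimated correlation). cry-dash, cry5 and per2 rose and ciarta and cry2 fell among clock genes (4 and 7 adjusted over the list alone, adjusted p = 0.129 for the list), ciarta not without 48 h replicate 2 (adjusted p = 0.076) and cry5 not without 48 h replicate 3 (0.0582). lef1, etv5a and id2a fell among 66 growth factor genes (3 higher and 3 lower adjusted over the list alone, adjusted p = 0.108 for the list), etv5a and id2a not without 48 h replicate 2 (adjusted p = 0.141 and 0.168).

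A further 5 genes with large changes at 48 h lost their calls without 1 array. insb fell by 5.76 (54.3-fold), hsd11b2, a steroid dehydrogenase gene, by 3.22 and smtnb by 2.14, with adjusted p of 0.107, 0.0542 and 0.0867 without 48 h replicate 3. tspan36 rose by 3.47 and the aquaglyceroporin gene aqp9b fell by 2.86, with adjusted p of 0.107 and 0.0895 without 48 h replicate 2.

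The 220 calls at 48 h became 81, 78 and 110 without control replicates 5, 6 and 7, and 54 without either 48 h replicate 2 or 3, and 92 without the 3 arrays rich in muscle RNA. They became 129 with the GAPDH covariate (GAPDH difference 5.31 ± 0.52 at 48 h), and 11 of 43 named calls passed whichever array was left out and 19 without the arrays rich in muscle RNA.

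Over the time course, 48 probe sets were higher and 35 lower at all 4 times, representing 37 and 25 named genes. Simulated unchanged groups gave 0, but such groups yield few calls at any time, so this 0 does not measure what the shared controls add. Of 1354 probe sets called at 1 or more times, 884 were called at exactly 1. per2, atf3, jun, ier5, crtac1a, gadd45ga, hspe1, hspd1, baxa, sdha and the ferritin gene fthl27 were called higher at all 4 times, and cita, id2a, ciarta, vim and lef1 lower. So were ddc, an enzyme of dopamine synthesis, which fell by 2.28, 2.58, 2.69 and 2.56 at the successive times, and nr2f1a, an orphan nuclear receptor gene, which fell by 3.38, 2.71, 2.87 and 3.62. At 48 h ddc did not pass without replicate 2 or 3 of that time (adjusted p = 0.0613 and 0.062), nor nr2f1a without control replicate 6 or 7 or 48 h replicate 3 or 4 (0.0731, 0.0563, 0.0542 and 0.0505). At 24 h fthl27, which rose by 3.32, did not pass without control replicate 6 or 24 h replicate 2 or 3 (0.0573, 0.0659 and 0.0597), and id2a had an adjusted p of 0.153 without 24 h replicate 2. The 48 h calls of atf3, hspe1, hspd1, baxa, ciarta and id2a also ended without 1 array. vim, an intermediate filament gene also listed for Müller glia, lay at 5.65 ± 0.43 in control and 3.77 ± 0.34 at 48 h.

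Pairs of times shared many calls in the same direction, and they share their control arrays. The 24 and 48 h calls had 75 higher and 85 lower probe sets in common and 0 opposite, where independent lists would share 2.15 and 2.08. Simulated unchanged groups shared 0, which follows from their few calls and does not measure what the shared controls add. The 6 and 12 h calls had 133 and 129 in common (6.41 and 6.54 for independent lists), and the 6 and 24 h calls 136 and 136 with 3 opposite (7.59 and 7.85). In common were also 66 and 62 at 6 and 48 h (2.86 and 2.84), 106 and 102 at 12 and 24 h with 3 opposite (4.81 and 4.80), and 55 and 51 at 12 and 48 h with 1 opposite (1.81 and 1.73). Changes at 24 and 48 h correlated across probe sets, which are not independent, with r = 0.838 against 0.498 in simulation (covariance 0.248 against 0.0454). For 6 and 12 h r was 0.659 against 0.5 (covariance 0.212 against 0.0457), for 6 and 24 h 0.629 against 0.498 (0.212 against 0.0454) and for 12 and 24 h 0.625 against 0.501 (0.196 against 0.0457). The 6 and 12 h changes were closest to simulation when paired with 48 h, with r = 0.553 against 0.499 (0.168 against 0.0456) and 0.535 against 0.5 (0.151 against 0.0457). The simulation drew its controls anew with independent probe sets, so it leaves out deviations that the real controls carry across many probe sets. The 3 controls cannot be split into separate sets of at least 2, so part of the excess may come from the shared controls.

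**Figure D5:**
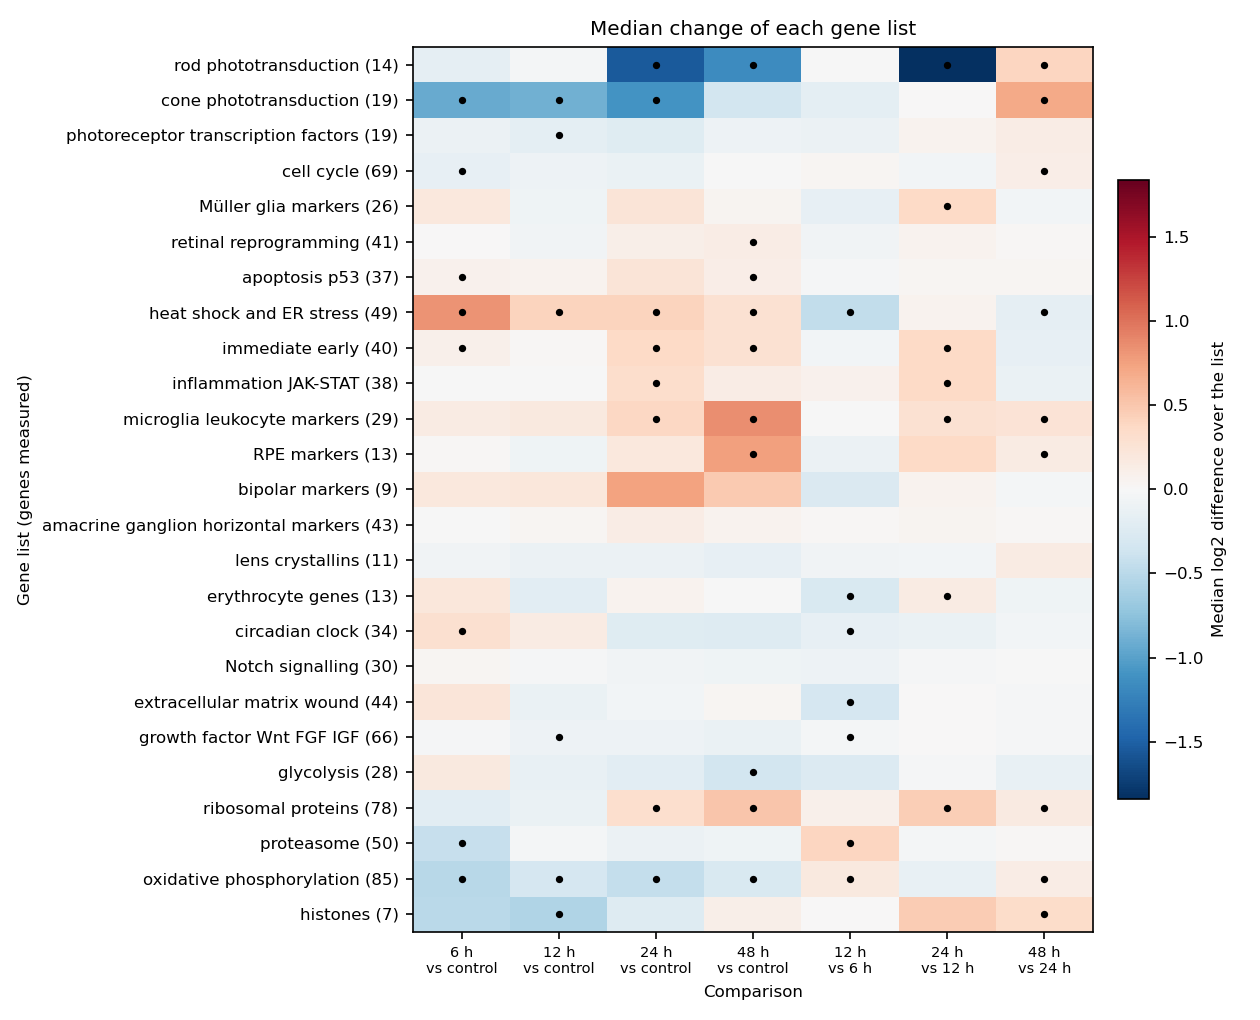
Median log2 difference (colour scale) of each of the 25 gene lists (y axis, number of genes in parentheses) in the 7 comparisons (x axis), with a dot where camera with a preset correlation gave an adjusted p under 0.05. The rod list had a median of -1.54 at 24 h and the heat shock list 0.82 at 6 h, and with an estimated correlation 0 lists passed.

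Between 6 and 12 h, limma called 167 probe sets, 82 higher and 85 lower at 12 h, in a direct test of the change within this interval. bhlhe40 and nr1d2b, which had not passed at 6 h, fell by 5.50 (adjusted p = 0.000487) and 4.46 (adjusted p = 0.000207), and pde6c by 2.03 (adjusted p = 0.000487). opn1mw2 rose by 2.61 (adjusted p = 0.0111) and ndrg1b by 4.47 ± 0.48 (adjusted p = 0.0019). With the muscle covariate the rise of opn1mw2 was 2.185 and did not pass (adjusted p = 0.0723), and without the 3 arrays rich in muscle RNA it was 1.76. mdka fell by 2.48, and the phosphatase gene dusp5, rad54l2 and mcl1b by 3.05, 2.84 and 1.26. podxl2, nfia and nptna rose by 4.69 ± 0.77, 2.47 and 2.25 and the cone gene guca1c fell by 2.78, with adjusted p of 0.065, 0.0646, 0.0623 and 0.154 without 12 h replicate 3.

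Among lists, 4 of 50 proteasome genes rose from 6 to 12 h (psma6a, psmd5, psmb4 and psmc1b, 0.89 for psma6a) and 0 fell, against 6 and 0 adjusted over the list alone (median 0.40, adjusted p = 4.01e-08, adjusted p = 0.373 with an estimated correlation). Of these psmd5, psmb4 and psmc1b did not pass without 12 h replicate 3 (adjusted p = 0.122, 0.161 and 0.111). With the muscle covariate neither psma6a nor the other 3 passed (adjusted p = 0.0687 for psma6a, and 0.19, 0.216 and 0.162 for psmd5, psmb4 and psmc1b). In that order their rises were 0.76, 0.73, 0.71 and 0.62 with the covariate, against 0.89, 0.87, 0.78 and 0.67 in the main fit. Without the 3 arrays rich in muscle RNA they were 0.70, 0.82, 0.68 and 0.69. All 4 rises were thus smaller with the covariate than in the main fit, and without those arrays only that of psmc1b was not smaller. Of 34 clock genes 6 fell and 0 rose, against 14 and 3 adjusted over the list alone (median -0.15, adjusted p = 4.18e-06, adjusted p = 0.373 with an estimated correlation). Of 49 heat shock genes hsf2 alone fell, by 1.83 (adjusted p = 0.0541 without 6 h replicate 2), against 10 adjusted over the list alone (median -0.46, adjusted p = 7.08e-06, adjusted p = 0.373 with an estimated correlation). Over the same interval the muscle list mean went from 5.54 ± 1.99 to 3.77 ± 0.55. The 167 calls became 92, 61 and 111 without 6 h replicate 3, 12 h replicate 3 and 48 h replicate 4, 32 with the muscle covariate and 31 without the 3 arrays rich in muscle RNA. Of 28 named calls 8 passed with that covariate and 7 without those arrays. A fit of only the 6 arrays called 5.

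Between 12 and 24 h, 57 probe sets rose and 104 fell, 161 in all. The clock repressor genes bhlhe41, bhlhe40 and nr1d2b rose by 6.34 (80.7-fold, adjusted p = 0.000315), 5.19 and 3.46 (adjusted p = 0.000356 for both), and nfil3-5 fell by 6.00 (63.8-fold, adjusted p = 0.000356). The rod genes gngt1 and gnb1b fell by 3.50 (adjusted p = 0.00337) and 2.58 (adjusted p = 0.00135). kif20a, mdka, nr2e3 and pde6c rose by 4.66, 3.18, 2.80 and 1.82. aqp8a.1 rose by 3.90 and ndrg1b fell by 3.58 (adjusted p = 0.00135 and 0.00337). rimkla fell by 4.46 ± 0.90, though not without 12 h replicate 4 (adjusted p = 0.133).

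Of 14 rod genes, 4 fell from 12 to 24 h (gngt1, gnb1a, gnb1b and rom1b) and nr2e3 rose, against 8 and 1 adjusted over the list alone (median -1.84, adjusted p = 3.02e-06, adjusted p = 0.373 with an estimated correlation). gnb1a fell by 3.68 and did not pass without 12 h replicate 4 (adjusted p = 0.0931). Of 34 clock genes 5 rose and 6 fell, against 9 and 9 adjusted over the list alone, and the list did not pass (median -0.12, adjusted p = 0.795). Ribosomal protein genes were higher in 72 of 78 cases with 0 called (median 0.46, adjusted p = 3.86e-08, adjusted p = 0.743 with an estimated correlation). The GAPDH difference went from 5.07 ± 0.24 to 5.64 ± 0.42, and with it as a covariate 94 probe sets were called, with the rod median at -1.25. The 161 calls became 71, 80, 93 and 100 without 12 h replicates 3 and 4 and 24 h replicates 2 and 3. A fit of only the 6 arrays called 35.

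Between 24 and 48 h, limma called 0 probe sets, with 776 at an unadjusted p under 0.05. With the GAPDH covariate, or without the 3 arrays rich in muscle RNA, 1 was called. The smallest adjusted p was 0.727, which tubb5 (3.36-fold higher), gap43 (1.86 ± 0.40), cirbpb (1.96 ± 0.44), sh2d3cb (-0.47 ± 0.10), xpnpep1 (-0.66 ± 0.14) and parp2 (-0.82 ± 0.18) shared. By list, cone genes lay higher at 48 h than at 24 h in 18 of 19 cases with 0 called (1 higher adjusted over the list alone, median 0.70, adjusted p = 7.47e-08, adjusted p = 0.373 with an estimated correlation).

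Across the 4 comparisons with control, 8, 6, 8 and 10 of 25 lists passed with the preset correlation and 0 with an estimated one, whose smallest adjusted p was 0.373. fry called 5 at 6 h (heat shock, cone, apoptosis, proteasome and histones) and 3 at 12 h (cone, growth factors and histones). It called 4 at 24 h (rod, cone, heat shock and growth factors) and 3 at 48 h (leukocytes, pigment epithelium and growth factors). With camera at the preset correlation, list calls of similar number also arose when the same arrays were regrouped, with up to 10, 10, 12 and 9 lists.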

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

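Of the tests below, those with the muscle or GAPDH covariate, that of the other photoreceptor genes and that of the hour of the day were chosen only after the result was seen. The results here drew attention because successive time points after light onset differed in a direct test of the difference.

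Between 12 and 6 h 167 probe sets differed, and between 24 and 12 h 161. Lists that passed camera with the preset correlation are given with their medians, which were not themselves tested. From 6 to 12 h they were heat shock and ER stress (-0.46), circadian clock (-0.15), proteasome (0.40), oxidative phosphorylation (0.18), erythrocytes (-0.28), extracellular matrix and wounding (-0.30) and growth factors (-0.042). From 12 to 24 h they were rod phototransduction (-1.84), ribosomal proteins (0.46), Müller glia (0.37), immediate early genes (0.37), inflammation (0.37), microglia and leukocytes (0.28) and erythrocytes (0.15). From 24 to 48 h they were cone (0.70) and rod phototransduction (0.40), cell cycle (0.13), heat shock and ER stress (-0.16), microglia and leukocytes (0.25), pigment epithelium (0.15), ribosomal proteins (0.17), oxidative phosphorylation (0.14) and histones (0.34). With an estimated correlation 0 of these passed, and with fry 2, the clock and proteasome lists from 6 to 12 h.

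Rod phototransduction genes lay lower at 24 h, by a list mean of -1.55. With the GAPDH difference as a covariate the mean was still -1.08 ± 0.293 (SE, 95% interval -1.74 to -0.417). This argues against RNA quality as the whole cause only as far as the GAPDH difference measures it. With the covariate 3 rod genes were called instead of 7, at a list median of -1.20. The GAPDH difference was itself highest at 24 h (5.64 ± 0.42, 4.98 ± 0.54 in control). The covariate thus overlaps with the group and may correct too little, so RNA quality stays open in part. Fewer photoreceptors of every kind among the captured cells cannot be told apart from a fall of rod transcripts, because the mean of 9 other photoreceptor genes also changed, by -0.746 ± 0.306 (-1.43 to -0.0637). These were the genes of the cone and transcription factor lists, other than opsins and rod genes, with a control level from 8 to 12. Cone genes outside that range included pde6c, which did not pass (-0.46), and rcvrn3, which rose by 2.45, so the 9 do not stand for all cone genes. The lesion, which the design names, stays open and was not tested apart from these.

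Heat shock genes lay higher and proteasome genes lower on average at 6 h, where muscle genes were high on several arrays. For heat shock, muscle RNA as the whole cause is argued against by the list mean with the muscle covariate. It was 1.05 (SE 0.187, 95% interval 0.631 to 1.48, 1.08 without the covariate). For the proteasome that mean was -0.356 (SE 0.124, -0.636 to -0.0764, -0.403 without it). With 3 muscle-rich arrays left out, the medians of heat shock and proteasome were 0.68 and -0.19, against 0.82 and -0.42 with all arrays. That fit has 1 array at 6 h, so it is imprecise. The muscle level was itself highest at 6 h, so the covariate overlaps with the group and may correct too little. For the proteasome the checks differ, so muscle RNA stays open there. Light, lesion and hour of the day changed together at 6 h and stay open.

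Clock genes differed from control by more at 12 h than at 24 h on average. RNA quality as the whole cause is argued against only as far as the GAPDH difference measures it. With that covariate 8 of the 11 clock genes that differed between 24 and 12 h were still called. The GAPDH difference was 5.07 ± 0.24 at 12 h and 5.64 ± 0.42 at 24 h. The covariate thus overlaps with these groups and may correct too little. The hour of the day at capture cannot be told apart from time after light onset, because the hours are not given and unlesioned retinas at matching hours were not analysed here. If the controls, titled T0, were taken at the hour of light onset, the 24 and 48 h samples would share their hour of the day. The mean absolute change of the 34 clock genes was 1.41, 1.76, 0.91 and 0.845 at the successive times, and that of all genes 0.4, 0.348, 0.395 and 0.344. On average clock genes thus still differed from control at 24 and 48 h by more than all genes did, in a comparison that was not matched on level. The ratio of 12 to 24 h lay at percentile 100 among random lists, but this restates the pattern and decides nothing about the hour.

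Regrouping the 15 arrays at random gave as many calls in the F test in 1 of 100 regroupings, the real one, with 918 against at most 40. This argues against a random split of these arrays, treated as independent samples, as the cause. Arrays of a group that share an animal or a batch could give it too, so differences of that kind are not excluded. The 6 arrays of a single comparison have 10 splits, so no share can fall under 0.1. The real split called 803, 500, 596, 220, 167 and 161 probe sets in the order of the comparisons, and the highest of the other splits 3, 1, 1, 1, 2 and 2, with 1 split reaching the real number in each. For 48 against 24 h the real split called 0, the highest other 11, and 10 splits called as many. Of the lists, 8, 6, 8, 10, 7, 7 and 9 passed in the real split and at most 10, 10, 12, 9, 8, 9 and 10 in another, with 4, 4, 2, 1, 3, 5 and 2 splits reaching the real number.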

How the results depend on the processing

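The covariates for GAPDH and muscle and the fits without 3 arrays rich in muscle RNA were tests chosen only after the results were seen. Most counts moved by over 1.5 times when 1 array was left out. RMA compresses differences among dim probe sets, which limits what can be seen there. The cause of a moved count was not tested except where fewer arrays entered the fit. The leave-one-out range was 434 to 855 probe sets at 6 h, 224 to 585 at 12 h, 156 to 954 at 24 h, 54 to 302 at 48 h, 61 to 194 for 12 against 6 h, 71 to 202 for 24 against 12 h, 0 to 1 for 48 against 24 h and 525 to 1208 for the F test. For lists it was 7 to 9 at 6 h, 5 to 7 at 12 h, 6 to 10 at 24 h, 9 to 11 at 48 h and 17 to 28 between successive times. Among named genes 909 of these fits kept the call and 555 lost it in the same direction.

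Array weights gave 768 at 12 h, 982 at 24 h and 356 at 48 h, and 1 adjustment over the 4 comparisons with control gave 337 at 48 h. Fits of only the 6 arrays gave 482 at 6 h, 227 at 24 h, 5 for 12 against 6 h and 35 for 24 against 12 h. Camera with an estimated correlation gave 0 lists in each comparison, and fry 5, 3, 4 and 3 against control and 2 between successive times. With the GAPDH covariate the counts were 113 at 24 h, 129 at 48 h, 94 for 24 against 12 h and 1 for 48 against 24 h, and with the muscle covariate 32 for 12 against 6 h. Without the 3 muscle-rich arrays they were 251, 243, 228 and 92 against control, 31 for 12 against 6 h, 1 for 48 against 24 h and 383 for the F test, where the lone array left at 6 h is assumed to vary like the other groups. There 130 of 244 named calls did not pass.

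The replicate block gave 88 for 12 against 6 h, 133 for 24 against 12 h and 0 for 48 against 24 h, and of the named calls between successive times 26 passed and 19 did not. The labels do not say whether equal numbers pair samples. Of same-numbered pairs, 8 of 18 correlated above 0.1 (from -0.11 to 0.25), and 6 of 12 lesioned arrays correlated best with their own number. Repeated quantile normalization, median centring, dim probe set filters and the intensity trend kept the totals per comparison within 1.5 times. The number higher moved by more for 12 against 6 h, from 82 to 49 with the intensity trend, and, with the stricter filter on dim probe sets, from 57 to 92 for 24 against 12 h and from 112 to 174 at 48 h. No pseudocount was varied, since the values are already log2.

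Replacing a gene's probe set by a dimmer one left 10 calls past the threshold and 41 under it in the same direction, and 13 values had the opposite sign. These 13 come from probe sets with mean levels from 2.46 to 3.194, and their adjusted p ran from 0.521 to 0.997, so their sign shows no reversal. They were per2 (-0.0034, -0.0439 and -0.198 at 12, 24 and 48 h), fosab (-0.0182 and -0.00683 at 24 h, -0.0283 at 48 h), kif20a (-0.0712 for 24 against 12 h, 0.017 for 12 against 6 h), samsn1a (-0.187 at 6 h, -0.114 at 12 h), cry-dash (-0.00381 at 24 h, 0.0869 for 12 against 6 h) and psmc1b (-0.116 for 12 against 6 h). The cause was not tested.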

Other observations

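The muscle genes were chosen only after the result was seen. The lists of this paragraph did not pass against control at any time. Of 26 Müller glia genes, vim fell at each time, hes6 fell at 12 h (adjusted p = 0.109 without 12 h replicate 3) and glulb rose at 24 h (0.0903 without 24 h replicate 3), and the list did not pass against control (adjusted p = 0.459, 0.477, 0.345 and 0.752). gfap lay at 2.93 ± 0.07 in control and 3.31 ± 0.15 at 48 h, and did not pass at any time. These levels lie near or below the array medians (3.279 to 3.366), where RMA compresses differences, so a change could be missed. Of 9 bipolar genes, samsn1a (2.24) and cabp5b (2.72) rose at 6 h, cabp5b not without control replicate 5 (adjusted p = 0.131), and the list did not pass (adjusted p = 0.102). Of 43 amacrine, ganglion and horizontal cell genes, the synuclein gene sncb fell by 1.70 at 6 h and 1.57 at 12 h, the latter not without control replicate 5 (adjusted p = 0.0874). The sodium pump gene atp1b2a fell by 0.56 at 6 h and 0.67 at 24 h, neither passing without control replicate 6 (adjusted p = 0.113 and 0.0664), and snap25b by 1.05 at 24 h (0.157 without 24 h replicate 2). This list had 2 lower at 6 h, 1 at 12 h, 2 at 24 h and 3 higher at 48 h, and did not pass (adjusted p = 0.899, 0.724, 0.508 and 0.205). Of 11 lens crystallins crygmxl2 fell by 0.55 at 24 h (adjusted p = 0.12 without control replicate 6), with the list not passing (adjusted p = 0.0633). The 13 erythrocyte genes had 0 calls against control, with haemoglobin gene hbaa1 at 7.65 ± 1.71 in control. Of 30 Notch genes psen2 rose by 1.43 at 6 h and hes6 fell at 12 h (adjusted p = 0.627 and 0.471 for the list). Of 44 matrix and wounding genes, tnn alone was called, lower by -0.47 at 12 h and -0.49 at 24 h (adjusted p = 0.378 and 0.899 for the list), and neither call passed without control replicate 6 (adjusted p = 0.155 and 0.127).

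Some genes of energy metabolism changed. The lactate dehydrogenase gene ldhbb fell by 2.02 at 6 h (adjusted p = 0.00627), 1.54 at 12 h and 1.47 at 24 h, the later calls ending without control replicate 6 and 24 h replicate 2 (adjusted p = 0.147 and 0.16). aldoaa rose by 1.27 at 6 h (adjusted p = 0.135 without control replicate 6). At 24 h 5 of 28 glycolysis genes fell, namely eno1b, ldhbb, tpi1a, pkma and pgam1b, eno1b and pkma not without 24 h replicate 2 (adjusted p = 0.0785 and 0.162) and tpi1a not without control replicate 6 (0.12), with the list not passing (adjusted p = 0.345).

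Some genes of other tissues varied between arrays of one group. For kera the arrays lay at 9.11, 8.69 and 7.95 in control, 2.79, 2.93 and 3.73 at 6 h, 2.32, 6.27 and 9.39 at 12 h, 2.48, 2.42 and 4.55 at 24 h and 3.74, 3.03 and 3.75 at 48 h. For insb, called lower at 6, 12 and 48 h, they lay at 9.46, 9.66 and 7.62 in control, 4.28, 4.35 and 2.92 at 6 h, 3.08, 3.45 and 3.89 at 12 h, 8.26, 6.73 and 2.70 at 24 h and 3.37, 2.50 and 3.58 at 48 h. The creatine kinase gene ckma lay at 11.04 on 6 h replicate 3, 8.429 on 6 h replicate 4 and 8.308 on control replicate 5.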
